A study of Mus musculus with 6 samples.

How the data were processed

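ATAC-seq was done on mouse R1 embryonic stem cells (ESC) and on neural progenitor cells (NPC), with 3 libraries of each, 6 libraries in all, per the labels. The titles of the NPC libraries also carry the name R1. ATAC-seq uses the Tn5 transposase to insert sequencing adapters into open chromatin, so the number of fragments over a site measures its accessibility. Per the labels' protocols, nuclei from cryopreserved cells were tagmented with Tn5 made in-house, amplified by PCR, size-selected on beads and sequenced in paired ends. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. The cell type in the labels gave each library its group.

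The values came from a single table of the authors' own comparison of NPC with ESC at high-confidence binding sites of SP1, a zinc-finger transcription factor that binds GC-rich promoter DNA. The submitters' processing notes name the mm10 genome build, BWA 2.1, Picard 2.23.8, MACS2 2.2.7 and SAMtools 1.9, without the role or settings of each. Per the submitters' processing notes, the authors also used DESeq2, whose column names the table carries. Its version and model are not given in the sources used here. How the SP1 sites were chosen, in which cells, and whether reads were shifted for the Tn5 offset are also not given in the sources used here. Any such step could change the counts per site, and the choice of sites in 1 cell type could change the balance of rises and falls.

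Each site in the authors' deposited table is 500 bp wide and has a mean signal, which is the normalized count averaged over the libraries per the file headers. The log2 fold change, its standard error, the p-value and the adjusted p-value are likewise the authors' deposited values. The direction, NPC over ESC, was read from the name under which the table was deposited, and no column states it. Values per library were not analysed here, so the depth of each library is unknown, no test between libraries was run, and no SD or n stands beside a site. The table lists 9001 sites on chromosome 1, chromosome 10 and chromosome 11, the last up to position 20195189, and says nothing of the rest of the genome. The ratios of adjusted p-value to p-value in the authors' deposited table are those of an adjustment over 103027 tested sites. With that number, 82.6% of the listed sites have a whole-number rank within 0.0001, against 0.0333% for 1 site more. The 9001 sites are 8.74% of that number. A p-value recomputed from the deposited log2 fold change over its standard error was at least as large as the deposited one at all 9001 sites, with a median ratio of 2.35. Fold changes shrunk towards 0 after testing would give this, and would understate the changes of sites with few reads. No source used here states such a step. Fold changes of sites at which 1 cell type had few or no reads depend on the authors' fit, so they are given as log2 values with their standard errors and not as bounds.

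A site counted as called when its deposited adjusted p-value was below 0.05, and as a rise or a fall by the sign of its log2 fold change. Gene positions came from a RefSeq table of assembly GRCm38.p6, which is mm10, with 2326 protein-coding genes in the listed regions. That table gave no strand, exons or sequence, so the planned promoter class (within 1 kb of a transcription start) could not be formed. In its place stood sites whose midpoint lay within 1000 bp of either end of a protein-coding gene. The remaining sites were split into those inside a gene body and those between genes. Exon, intron and UTR positions, base composition and SP1 motif numbers were not analysed here. Coordinates are printed as the table gives them, and it does not say whether they count from 0 or 1. For gene lists, a site was assigned to the protein-coding gene with the nearest end within 50000 bp, which placed 6135 sites (68.2%) at 1854 genes. Sites inside a long gene but farther than this from both of its ends stayed out of that gene's count. Nearness does not show that a site acts on that gene.

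Classes of sites were compared with Fisher's exact test, two-sided, with percentages given 95% Wilson intervals that cover counting error over sites. Sites are not independent replicates, and 425 of them overlap the next site. The 15 gene lists, the thresholds, the rule for naming sites and the alternatives, except those listed as added, were fixed before the data were examined. Alternatives added after the data were seen were adjustment over the listed sites, p-values recomputed from the fold change over its standard error, and centring on the gene-end median. Others were 1 site per overlap group, leaving out chromosome 11, the ends of all RefSeq genes, deciles of mean signal, random genes in place of random sites, and the relation to signal within each class of sites. Lists with at least 5 sites were tested by setting the median log2 fold change of their sites against 10000 random sets of as many listed sites matched on deciles of mean signal. The test was two-sided, with Benjamini-Hochberg adjustment over the 12 lists tested. Its p-value counted the random sets whose median lay at least as far from the centre of all random medians as the list's, in either direction. Random medians reached farther below that centre than above it, so the p-value of a rise also counted random sets that lay low. Random sets treat the sites of a gene as independent, so random genes with similar numbers of sites were added as an alternative after the data were seen. These genes were not matched on mean signal, so that alternative differs from the main test in this as well. Its p-value was formed in the same way. Tested on simulated data, lists of 20 of the 9001 sites were called in 5% of 200 draws with no shift, in 28% with a log2 shift of -1 and in 83% with a shift of -2. These draws took sites independently from shuffled values and used an unadjusted p below 0.05. They therefore do not give the error rate or power for the real lists, whose sites cluster at a few genes and whose p-values were adjusted. The rule named the 10 largest rises and the 10 largest falls among called sites with a mean signal at or above the median, 1 per nearest gene at any distance. It also named up to 4 genes per list by smallest adjusted p-value. Pou5f1, Nanog, Sox2, Pax6, Nes and Sp1, which the rule also named, lie outside the listed regions and were not analysed here. Values of 1 further gene that the rule named are not reported here on their own, and its sites stay in the counts. Alternatives covered stricter thresholds, centring of the fold changes, low-signal sites, gene-end distance, overlapping sites and the partly listed chromosome. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, with plots from matplotlib 3.10.9.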

Results

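Chromatin accessibility was measured by ATAC-seq in mouse R1 embryonic stem cells (ESC), a pluripotent line, and in neural progenitor cells (NPC), with 3 libraries of each. The NPC libraries are also labelled R1. The series belongs to a study of the apparent binding affinities of transcription factors across the genome. The comparison asks how accessible the high-confidence sites of SP1 are in each cell type. The authors' deposited table gives 9001 such sites on chromosome 1 (4902 sites), chromosome 10 (3595) and the first part of chromosome 11 (504). Mean signal, the normalized count averaged over the libraries, had a median of 5.78 per site, with quartiles of 3.38 and 11.4 and a range of 0.467 to 170. Depth per library was not analysed here, and these low counts limit the precision at single sites.

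SP1 sites near genes of the pluripotent state were less accessible in NPC than in ESC. Sites near the 4 neural progenitor genes covered had a median log2 fold change of 1.81, a shift that passed the test against random sites and not against random genes (adjusted permutation p = 0.0357 and 0.116). All 8 sites assigned to Tfcp2l1, a transcription factor of naive pluripotency, fell. So did the pair of sites at Nodal, which encodes a TGF-beta family ligand. At the homeobox gene Meis1, 5 of 7 sites rose and 1 fell. The gene-end site of Fabp7, the fatty acid-binding protein of radial glia, rose by 3.54 ± 0.42 (SE) on the log2 scale, or 11.6-fold, with an adjusted p of 2.28e-14 in the authors' deposited table. Across all SP1 sites, 2934 (32.6%, 95% Wilson interval 31.6 to 33.6) fell in NPC against ESC and 2052 (22.8%, 21.9 to 23.7) rose at the authors' adjusted p below 0.05.

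The remaining 4015 sites were not called. Among called sites the median rise was 3.03 and the median fall -3.24 on the log2 scale, 8.17-fold and 9.46-fold, and 1829 of the rises and 2892 of the falls exceeded a log2 change of 1. The median log2 fold change of all sites was -0.29. With fold changes centred on that median, which balances the directions by construction, and p-values recomputed, 2081 sites rose and 2049 fell, where the recomputed p-values alone gave 1688 and 2382. Centred on the gene-end median, 0.18, an alternative added after the data were seen, 1467 rose and 2594 fell. On chromosome 1, 1130 sites rose and 1646 fell, on chromosome 10 the counts were 762 and 1150, and on the listed part of chromosome 11 they were 160 and 138.

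The largest rises among called sites of at least median signal, 1 per nearest gene, lay away from gene ends. The site nearest Nek2, a centrosomal kinase, at chromosome 1 from 191808758 to 191809258 and 12.4 kb from the gene, rose by 7.15 ± 1.13 (SE) on the log2 scale, adjusted p = 1.19e-09 in the authors' deposited table. A site 299 kb from Meis1, on chromosome 11 from 18581428 to 18581928 and between genes, rose by 7.14 ± 1.13 in the authors' deposited table (adjusted p = 1.26e-09). Next in the authors' deposited table came the site nearest Timp3, a metalloproteinase inhibitor whose site lies within Syn3 (7.12). A site 119 kb from Fhl2, which encodes a LIM-domain protein, had 7.10 in the authors' deposited table. Tbc1d30 (6.95, 57.5 kb away) and Dpt, the gene of the matrix protein dermatopontin (6.80), followed in the authors' deposited table. Nearest Arhgef4 and inside Prrx1, a mesenchymal homeobox gene, the authors' deposited table gave 6.73 and 6.71. The last of the 10 lay nearest Adamts14, a secreted metalloproteinase (6.64), and inside Srgap1, a GTPase-activating protein of the Slit-Robo pathway (6.62, log2 values of the authors' deposited table).

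Among called sites of at least median signal, taking 1 per nearest gene, the largest fall was inside Dusp27, at chromosome 1 from 166125162 to 166125662 and 2.49 kb from the gene's end, with a log2 fold change of -7.57 ± 1.12 (SE) and an adjusted p of 9.79e-11 in the authors' deposited table. A site inside Hs3st5, a heparan sulfate sulfotransferase gene, followed with -7.39 ± 1.13 in the authors' deposited table. Then came the sites nearest Mrpl42, a mitochondrial ribosomal protein gene (-7.03), and Zfp648, 120 kb away (-6.99), in the authors' deposited table. The site nearest Cntnap5a, 1725 kb away, had -6.94 in the authors' deposited table. Aspm, whose spindle protein is needed for the divisions of neural progenitors, had the one gene-end site among these 10 falls. It lay 770 bp from the gene on chromosome 1 from 139494608 to 139495108, at -6.64 ± 0.98 in the authors' deposited table (adjusted p = 1.70e-10). Other falls in the authors' deposited table were at Gli2, a transcription factor of hedgehog signalling (-6.88, 21.3 kb from the gene), and inside Nmnat2, an axonal NAD-synthesising enzyme (-6.67). The last were inside Akap12, a protein kinase A anchor (-6.50), and nearest Brinp3, 68.6 kb away (-6.49), also in the authors' deposited table. All 20 of these fold changes had a standard error of 0.98 to 1.14. Such sizes depend on how the authors' fit treats sites with few reads in 1 cell type.

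**Figure D1:**
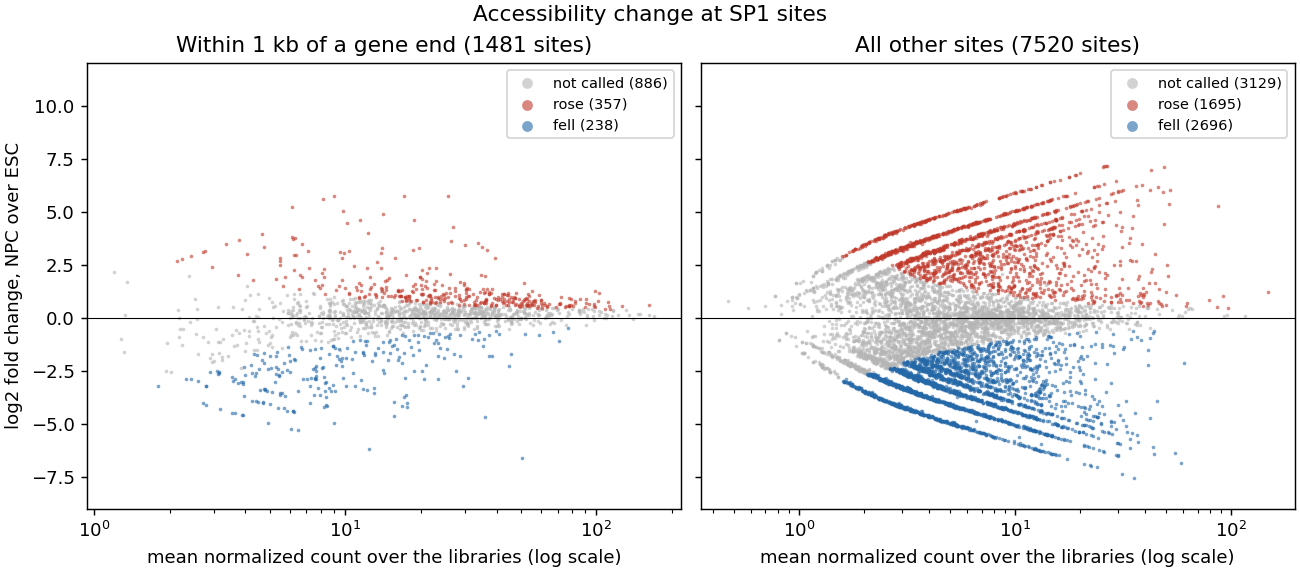
Log2 fold change of NPC over ESC (y axis) against mean normalized count over the libraries (x axis, log scale) for each SP1 site, at the 1481 sites within 1 kb of a gene end (left) and the other 7520 sites (right), with rises in red, falls in blue and sites not called in grey. Gene-end sites had a median mean signal of 18.1 and a median absolute log2 fold change of 0.57, against 4.99 and 2.27 at the other sites.

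Sites near the ends of genes lost accessibility less often than the others. Of 1481 gene-end sites, 238 fell (16.1%, 95% Wilson interval 14.3 to 18.0) and 357 rose (24.1%, 95% Wilson interval 22 to 26.4). Of the 7520 other sites 2696 fell (35.9%) and 1695 rose (22.5%). The odds of a fall were 0.343 times those elsewhere (95% interval 0.296 to 0.397, Fisher's exact test, two-sided, p = 8.56e-55, across sites, which are not replicates). Rises were not called different between the classes (odds ratio 1.09, 0.958 to 1.24, Fisher's exact test, p = 0.198). That second odds ratio depended on the setting. It passed the threshold at 1.22 for gene ends within 500 bp and 1.66 with centring on all sites, and turned to 0.514 when a log2 change above 1 was also required and to 0.543 within deciles of mean signal, the last added after the data were seen. Called gene-end rises were also smaller, with a median of 1.03 against 3.03 for all called rises, and the median gene-end fall was -2.43.

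Within gene bodies 900 of 3637 sites rose (24.7%) and 1208 fell (33.2%), and between genes 795 of 3883 rose (20.5%) and 1488 fell (38.3%). Falls were more frequent between genes than in gene bodies (odds ratio 1.25, 1.14 to 1.37, Fisher's exact test, p = 4.29e-06) and rises less frequent (0.783, p = 9.88e-06, same exact test). The share of falls was 37.7% from 1 to 10 kb of a gene end, 34.2% from 10 to 50 kb, 34.4% from 50 to 200 kb and 40.2% beyond. Across sites, log2 fold change rose weakly with mean signal (Spearman rho 0.111, Pearson r 0.0996, permutation p = 1e-04 for rho, the smallest the permutations can give). Without the lowest 25% of sites by signal rho was 0.172. Within classes, a split added after the data were seen, rho was 0.293 among gene-end sites and 0.0364 among the others (permutation p = 0.0016 for the latter).

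**Figure D2:**
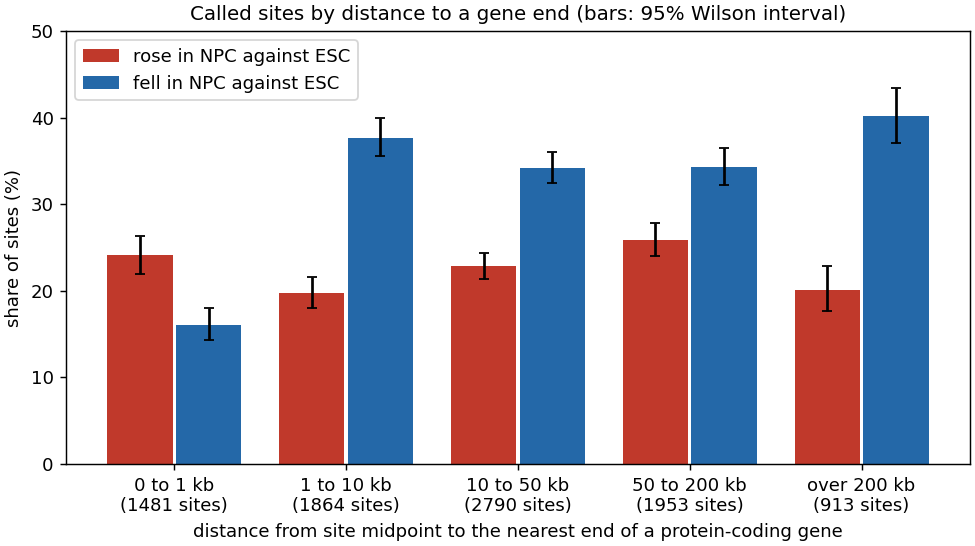
Share of SP1 sites (y axis, percent) that rose (red) or fell (blue) in NPC against ESC, by distance from the site's midpoint to the nearest end of a protein-coding gene (x axis), with 95% Wilson intervals as error bars. Falls made up 16.1% of sites within 1 kb and between 34.2% and 40.2% in the farther classes.

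Of the pluripotency list, 7 genes had sites in the listed regions, and 22 of their 29 sites fell, 1 rose and 6 were not called. The list's median log2 fold change was -3.16 (mean -2.88), against a median of -0.26 for random sets of sites with similar signal (95% of sets from -1.72 to 0.50, permutation p = 1e-04, the smallest the sets can give, adjusted p = 0.0012 over 12 lists). Inside Tfcp2l1 a site at chromosome 1 from 118645652 to 118646152 had a log2 fold change of -5.84 ± 1.16 (SE, adjusted p = 1.43e-06), and the gene-end site, 23 bp from the gene, one of -1.77 ± 0.41, in the authors' deposited table. Prdm14, a regulator of pluripotency and germ cell fate, had falls at 5 of 7 sites, that of smallest adjusted p with -4.50 ± 0.87 in the authors' deposited table. The site nearest Lefty1, a Nodal antagonist, fell by 5.29 ± 1.16 on the log2 scale in the authors' deposited table, and the single sites of Lefty2 and of Dnmt3l, the cofactor of de novo DNA methylation, fell too. Nr5a2, a nuclear receptor gene, had 4 falls among 9 sites, the strongest at -4.83 ± 0.75 (adjusted p = 3.53e-09), and the list's lone rise, 1.36 ± 0.46, in the authors' deposited table.

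The neural progenitor list had 20 sites at 4 genes, of which 13 rose, 2 fell and 5 were not called. Its median log2 fold change was 1.81 (mean 1.77, permutation p = 0.0119, adjusted p = 0.0357). Of the random site sets, 99.91% had a lower median, and most sets counted in that p-value lay at the low end instead. The call was lost against random genes with similar numbers of sites, not matched on signal (adjusted permutation p = 0.116), and with 1 site per gene (median 2.11, adjusted permutation p = 0.144). It held with the 3 gene-end sites alone (median 3.54, adjusted permutation p = 0.0070) and with 1 site per overlap group, added after the data were seen (adjusted permutation p = 0.0228). Both settings again treat the sites of a gene as independent. Meis1 and Pou3f3 had no gene-end site, and 3 sites are fewer than the 5 required in the main test. Values of 1.81 ± 0.33 at Meis1 (adjusted p = 5.66e-07) and 3.01 ± 0.78 at Pou3f3, a POU-domain transcription factor gene of the nervous system (adjusted p = 0.000311), stood in the authors' deposited table. Of the neuron list, 5 of 12 sites rose and 3 fell (median 0.97, adjusted permutation p = 0.226). At Map2, a dendritic microtubule protein gene, 4 of 8 sites rose and 2 fell, and the leading site rose by 3.74 ± 0.79 in the authors' deposited table. At Syt1, the calcium sensor of synaptic vesicles, 1 of 4 sites rose (4.35 ± 1.02), 1 fell (-1.96 ± 0.66) and the others had -1.47 ± 0.93 and -0.91 ± 0.60 in the authors' deposited table.

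The lists of markers of other lineages with sites in the listed regions had them at 1 or 2 genes. The glia list rested on Gja1 alone, the gene of connexin 43, with 4 of 7 sites falling and 1 rising (median -3.46, adjusted permutation p = 0.0357). Against random single genes with a similar number of sites, a test added after the data were seen, that call was lost (adjusted permutation p = 0.0596 over the glia and mesenchymal lists). A site 36.1 kb from Gja1 fell by 5.10 ± 0.68 (adjusted p = 3.89e-12) while the site 27 bp from the gene rose by 0.74 ± 0.37 (adjusted p = 0.0345) in the authors' deposited table. The mesenchymal list rested on Fn1 alone, the fibronectin gene, where 5 of 6 sites fell (median -3.69, adjusted permutation p = 0.0216, and 0.0320 against random single genes), with -6.06 ± 1.15 at the leading site, inside the gene, in the authors' deposited table. The site at the end of Fn1 also fell, 2.00-fold in the authors' deposited table. Of the mesoderm and endoderm list 3 of 5 sites fell (median -2.65, adjusted permutation p = 0.153), all at Sox17, an endoderm transcription factor gene with -3.91 ± 0.65 at its leading site in the authors' deposited table. Mixl1, a primitive streak homeobox gene, had a log2 fold change of 1.93 ± 1.68 in the authors' deposited table (adjusted p = 0.167). The 3 sites of the germline list were too few to test. They fell at the end of Sycp3, a synaptonemal complex gene (-4.00 ± 1.23), fell at the end of the piRNA pathway gene Mael (-4.12 ± 1.34) and rose 5.75 kb from it (2.89 ± 1.01) in the authors' deposited table. No member of the epithelial list or of the Hox clusters lay in the listed regions.

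**Figure D3:**
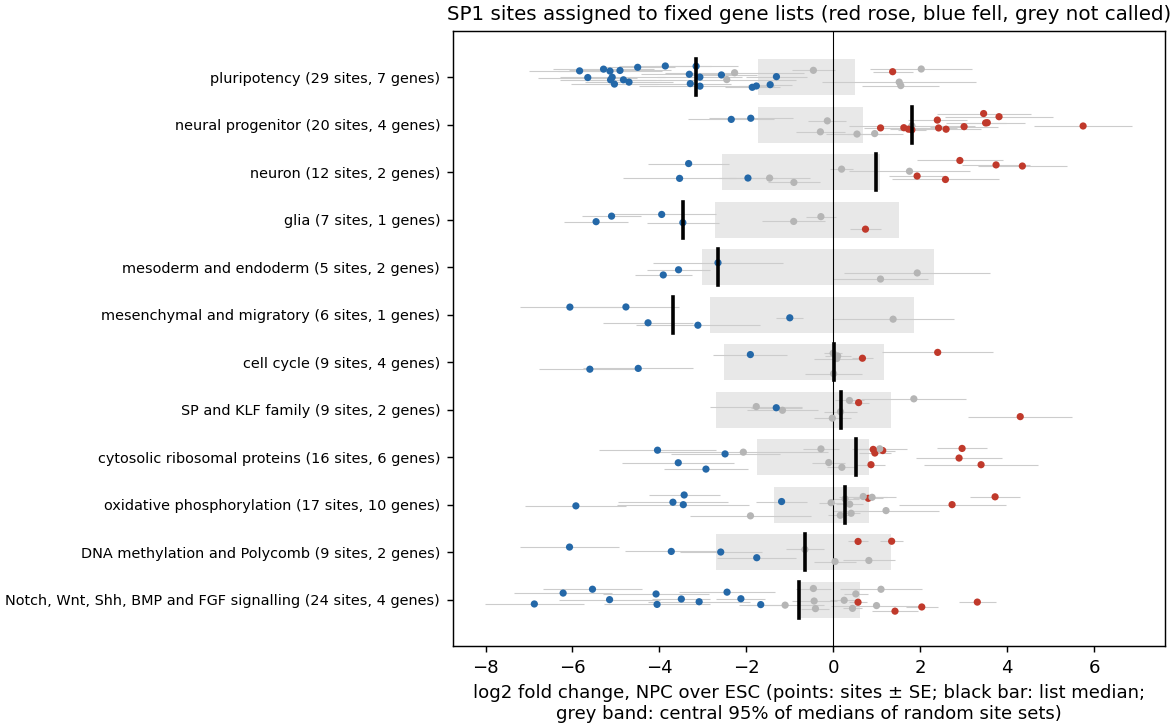
Log2 fold change of NPC over ESC (x axis) of each SP1 site assigned to the 12 tested gene lists (y axis), with points ± SE in red for rises, blue for falls and grey for sites not called. Black bars mark list medians and grey bands the range that holds 95% of the medians of random site sets. The pluripotency (-3.16), glia (-3.46), mesenchymal (-3.69) and neural progenitor (1.81) medians lay outside their bands.

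The signalling list did not pass the test, and within it Gli2 and Dusp6 had called sites in both directions. Of 24 sites at Gli2, Gli1, Fzd5 and Dusp6, 11 fell, 4 rose and 9 were not called (median -0.78, permutation p = 0.0303, adjusted p = 0.0727). The median was 0.48 with 1 site per gene and also with gene-end sites alone, of opposite sign, and -0.46 with 1 site per overlap group, none of them called. Gli2 had 8 falls and 2 rises among its 13 assigned sites. Counting every site inside the gene or within 50 kb of it, 8 of 22 rose and 11 fell. The lean to falls at Gli2, which holds 13 of the list's 24 sites, thus depends on the assignment rule. Inside the gene, on chromosome 1 from 119033812 to 119034312, a site rose by 3.31 ± 0.43 (SE, adjusted p = 1.65e-12) in the authors' deposited table. The fall 21.3 kb from Gli2 lay on the same chromosome from 119075410 to 119075910 in the authors' deposited table. Fzd5, a Wnt receptor gene, had a fall of -5.54 ± 1.14 inside the gene, and a site 1.99 kb from Dusp6, a phosphatase gene of the FGF pathway, rose by 2.03 ± 0.36 in the authors' deposited table. Both sites of Gli1 were uncalled, with log2 fold changes of -0.46 ± 0.40 and 0.25 ± 0.33 in the authors' deposited table.

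**Figure D4:**
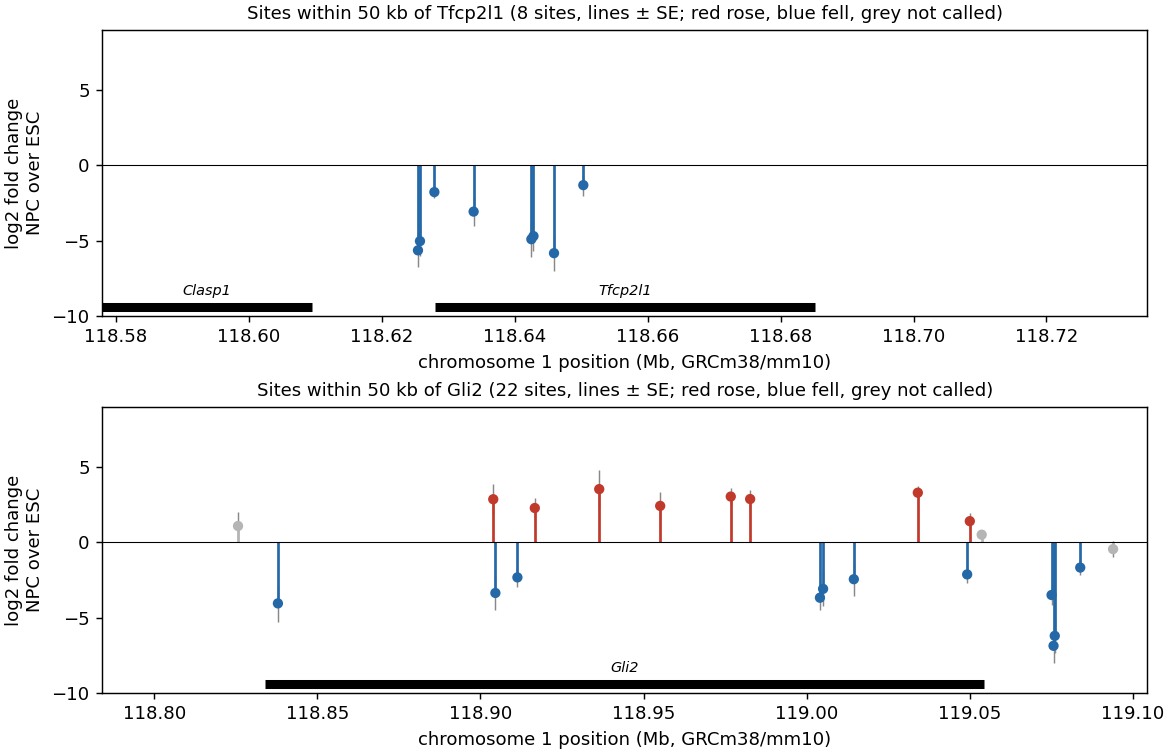
Log2 fold change of NPC over ESC ± SE (y axis) of SP1 sites by position (x axis, Mb, mm10) within 50 kb of Tfcp2l1 and Gli2, with rises in red, falls in blue, sites not called in grey and genes as black bars. All 8 sites at Tfcp2l1 fell, and at Gli2 8 of 22 rose and 11 fell.

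Lists of general cell functions showed no shift that passed the test. Ribosomal protein genes had 7 rises and 4 falls among 16 sites (median 0.53, mean -0.07, so of opposite sign, adjusted permutation p = 0.397), and a median of 0.046 with 1 site per overlap group. Their gene-end sites at Rpl7 rose (1.14 ± 0.29 at the stronger), and a site 26.1 kb from Rpl37a rose by 2.96 ± 0.58, in the authors' deposited table. Falls were at sites inside neighbouring genes, Tbc1d8 near Rpl31 (-4.04 ± 1.35) and Map7 near Rpl32l (-2.93 ± 0.98), in the authors' deposited table. Another site inside Tbc1d8 near Rpl31 rose by 3.40 ± 1.32 (adjusted p = 0.00807) in the authors' deposited table. Oxidative phosphorylation genes had 3 rises and 5 falls among 17 sites (median 0.27, mean -0.49, again of opposite sign, adjusted permutation p = 0.663). Among them, sites rose near Ndufa12 (3.72 ± 0.58) and at the end of Cox5b (0.81 ± 0.35) and fell near Ndufa10 (-5.92 ± 1.16) and Ndufs1 (-3.43 ± 0.81), all in the authors' deposited table. Cell cycle genes had 2 rises and 3 falls among 9 sites (median 0.0070, mean -0.97, adjusted permutation p = 0.913). Falls lay at Cdk1, the mitotic kinase gene (-4.49 ± 1.27), inside Pmel next to Cdk2 (-5.60 ± 1.17) and inside Mcm6 (-1.91 ± 0.85) in the authors' deposited table. The end of Mcm3, like Mcm6 a replicative helicase gene, rose by 0.67 ± 0.23 in the authors' deposited table.

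Of the SP and KLF family itself, 2 of 9 sites rose and 1 fell (median 0.17, adjusted permutation p = 0.768), with 4.30 ± 1.19 inside Klf7 and -1.31 ± 0.59 near Klf16 in the authors' deposited table. DNA methylation and Polycomb genes had 2 rises and 4 falls among 9 sites (median -0.65, adjusted permutation p = 0.494). A site 14.9 kb from Rnf2, a Polycomb ubiquitin ligase gene, fell by 6.07 ± 1.15 on the log2 scale while its gene-end site rose by 0.57 ± 0.23 in the authors' deposited table. Inside Tet1, a methylcytosine dioxygenase gene, a site rose by 1.34 ± 0.27 and another fell by 2.59 ± 0.94, and a gene-end site fell by 1.76 ± 0.91, in the authors' deposited table. Its other gene-end sites, with 0.04 ± 0.49 and -0.65 ± 0.44 in the authors' deposited table, were not called. Adjusted over the list alone, the counts were 3 rises and 23 falls for the pluripotency list and 6 rises and 11 falls for the signalling list. For the other lists with sites they equalled those above.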

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

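No paired analysis was possible because the table holds the authors' comparison and no values per library, so the shared replicate numbers of the groups could not be used. For the same reason another test tool, size factors against TMM, library totals, no low-count filter, pseudocounts, an estimated correlation for gene lists, leaving out each library and other splits of the 6 libraries were not run. The number of called sites, 4986, lay between 3576 (adjusted p below 0.01) and 5001 (adjusted over the listed sites, an added alternative) under the alternatives tried. Both centrings also recomputed the p-values, which alone gave 4070 calls, 41.5% of them rises, and an odds ratio of a rise near gene ends of 1.01. Rises made up 41.2% of calls, 50.4% with fold changes centred on the median of all sites (a shift of 0.29), which balances the directions by construction, and 36.1% with centring on the gene-end median, 0.18, an alternative added after the data were seen. The odds ratio of a fall near gene ends stayed between 0.305 and 0.460. The odds ratio of a rise there, 1.09 without a call, passed the threshold at 1.22 for gene ends within 500 bp, 1.66 with centring on all sites and 1.14 with the ends of all RefSeq genes. It reversed to 0.514 with a log2 change above 1 required, 0.705 with centring on gene-end sites and 0.543 within deciles of mean signal; the last 2 and the RefSeq set were chosen after seeing the data. Requiring a larger change removes the small rises typical of gene ends; the cause of the other reversals was not tested. The neural progenitor list lost its call with 1 site per gene (median 2.11, adjusted permutation p = 0.144), where 4 sites were left, and against random genes (median 1.81, adjusted permutation p = 0.116), a comparison added after seeing the data. The glia list lost its call against random single genes (median -3.46, adjusted permutation p = 0.0596), also added. Of the 56 named sites, 54 were called, and between 51 and 54 of these kept their call under each setting; leaving out the lowest 25% of mean signal removed 2 of them. Those near Mcm3, Mcm6, Klf16 and Cox5b lost it under some. A median mean signal of 5.78 limits what single sites can show.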

Other observations

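The patterns in this part were found in the table itself. The tests of overlapping reads, mean signal and scaling (of which the centring on all sites was planned as an alternative), the counts of genes with a single direction and the gene-end comparison within genes were chosen only after those results had been seen. Among 119 genes with at least 5 called sites that do not overlap, 21 had all of them moving in a single direction, 16 down and 5 up, against a mean of 6.94 (95% of shuffles 2 to 12) when directions were shuffled among sites (permutation p = 0.001, the smallest 1000 shuffles can give). Directions were shuffled site by site, which breaks the agreement between neighbouring sites described below. Of 231 called pairs 0.5 to 2 kb apart, 77.9% had the same direction. The excess is thus not shown to be separate from that agreement. The genes below were chosen after their values were seen. Their medians cover called sites only, and except at Tfap2b and Rgs8 further sites were not called. Counting all sites that do not overlap, Col18a1 had 15, Akap12 11, E2f7 10 and Tgfb2 9. All called sites fell at Akap12 (8 sites, median log2 fold change -4.33) and at Col18a1, the gene of a basement membrane collagen (8 sites, -3.37). They also fell at E2f7, an atypical E2F repressor gene (6 sites, -2.79), Myb, a transcription factor gene of blood progenitors (5, -2.90), and Tfap2b, an AP-2 factor gene of the neural crest (5, -2.36). All called sites rose at Znrf3, a ubiquitin ligase gene that restrains Wnt receptors (6 sites, 3.83), Prox1, a homeobox gene of differentiating neurons and lymphatic vessels (5, 3.98), Tgfb2, a TGF-beta ligand gene (5, 4.52), Serpine2, a protease inhibitor gene (5, 4.61), and Rgs8 (5, 2.93).

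Other genes held strong changes of either sign. Mixed directions were also what shuffling gave at most of the 119 genes, with a mean of 6.94 in a single direction. Reep3 had 6 rises and 5 falls, from -4.98 to 4.49, Spred2, an inhibitor of Ras signalling, 7 and 4, and Eya1, a transcriptional cofactor gene of sensory organs, 4 and 3. Epha4 and Plxna2, which encode axon guidance receptors, had 3 rises and 3 falls each. Across 810 genes, the mean log2 fold change of gene-end sites was weakly related to that of sites from 2 to 50 kb away (Spearman rho 0.0924, Pearson r 0.107, permutation p = 0.0092, across genes, which are not replicates).

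Neighbouring SP1 sites tended to change in the same direction. Reads shared by overlapping sites may account for the 99.5% of 187 overlapping called pairs with the same direction, but not for the whole pattern. Of 1874 called pairs from 2 to 50 kb apart, 59.8% had the same direction, against 51.8% (95% of shuffles 49.5 to 54.1) among sites shuffled within class and signal. Trends over stretches of 10 Mb gave 53.0% (50.8 to 55.1) in shuffles within such windows, so they are not the whole cause either (permutation p = 0.0005 for both shuffles, the smallest that 2000 can give). For the 569 called pairs of neighbours over 50 kb apart the share was 63.6% (shuffled mean 52.4% within class and signal), and no biological explanation was tested.

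Fewer falls near gene ends could come from the higher signal there, or from a single scaling shift of all fold changes. Within deciles of mean signal the odds ratio of a fall near gene ends was 0.443 (95% interval 0.378 to 0.518), still below 1. Pooled over the same deciles, rises were also fewer near gene ends (odds ratio 0.543, 95% interval 0.463 to 0.637). In these pooled values the deficit was thus not particular to falls. After centring, the higher of the odds ratios of a fall from both centrings was 0.401, so neither explanation accounts for the whole pattern. How the SP1 sites were selected stays open and was not tested: if sites away from genes had been chosen by SP1 binding in ESC, more of them could lose accessibility in NPC than gain it. A cell-type difference that spares gene-end sites of higher signal stays open as well.

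Gene-end sites on the listed part of chromosome 11 lay above those on chromosomes 1 and 10, with medians of 0.53 (87 sites) and 0.18 (1394 sites), a difference of 0.349 (95% interval 0.135 to 0.547, permutation p = 0.0003). Chance among regions of this size could account for it, since 6.01% of 283 overlapping stretches of the same length on the other chromosomes had a median at least as high. A gain in copy number of chromosome 11 in NPC, or a loss in ESC, cannot be told apart from it. Sites away from gene ends also lay higher, by 0.588 (0.318 to 0.858). The 66 gene-end sites of the first 10 Mb lay higher by 0.457 (0.231 to 0.751). But the 21 gene-end sites beyond 10 Mb gave -0.280 (-1.01 to 0.323), too wide an interval to decide. The rest of chromosome 11 was not analysed here.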
